A study of Mus musculus with 6 samples.

How the data were processed

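Group 2 innate lymphoid cells (ILC2s) are tissue lymphocytes that make type 2 cytokines without an antigen receptor. Mouse ILC2s were sorted through a Chat negative or a Chat positive gate, with 3 samples from each gate, per the labels. Chat encodes choline acetyltransferase, the enzyme that makes acetylcholine. Libraries were prepared from the sorted cells with a SMARTer ultra-low-input kit, per the labels' protocols. The submitters' processing notes name CASAVA 1.8.2, STAR 2.3.0 and the mm10 mouse build. The program that counted reads per gene, its strand setting, the tissue, any stimulus given to the mice and the way Chat was detected for sorting are not given in the sources used here. Without a known strand setting, reads of genes that overlap on opposite strands cannot be told apart.

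The deposited table holds raw read counts per gene for 27179 Entrez gene IDs, in 1 column per library, and the authors applied no normalisation to them, judging from whole numbers with a different sum in each column. Totals ran from 37154269 to 50361306 counts per library. Of the IDs, 25275 matched the RefSeq gene table of GRCm38.p6, the assembly that mm10 is made from, and took their symbols and coordinates from it. The other 1904 IDs held at most 0.222% of the counts of a library and stayed in the library totals and tests. Transcript length and GC content were those of the longest GENCODE vM21 transcript of a gene, known for 93.2% of the genes tested below. Within a gate, no pair of libraries agreed within sampling noise (chi-square per degree of freedom at least 31.4), so all 6 were kept as separate samples. The labels do not say that the samples of a gate came from separate animals, so p-values measure only the spread between these samples, which may be technical.

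Genes were kept by edgeR's filterByExpr, which left 12967. Library sizes were scaled with TMM factors, and CPM below are counts relative to the scaled library size (edgeR cpm), given as mean ± SD over 3 libraries. Each gene was tested with edgeR's quasi-likelihood F-test with robust dispersions, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 5%. The fit compared the gates without a term for the replicate number. Log2 changes are Chat positive minus Chat negative, with the standard error (SE) that the F statistic implies. The analysis ran in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Library measures were compared with two-sided exact permutation tests of 3 against 3, which have 20 arrangements and a smallest possible p of 0.1.

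Before the data were examined, 35 gene lists were fixed, covering acetylcholine handling, ILC2 programs, metabolism, stress and cell cycle, and markers of other cell types the gates could hold. The 31 lists with at least 5 tested members were tested with camera with a preset correlation of 0.01, adjusted over the lists by Benjamini-Hochberg. Also fixed before the data were examined were the model, the alternatives given below as chosen beforehand and the rule for naming genes. That rule takes Chat and up to 8 members of each acetylcholine list by p, and in each direction the 12 genes with the largest changes past the threshold, a mean of at least 10 CPM in the higher gate, no overlap between the gates and a symbol that is not provisional, a receptor segment or a pseudogene. With fewer than 10 of those in a direction, it takes the 10 with the smallest p, named as not passing. It adds up to 4 members per list by p, the 2 most abundant members of each marker list, and a fixed set of ILC2 genes. 1 gene that the rule names is not reported here.

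The gates share the replicate numbers 1 to 3. Libraries with the same number deviated from their gate's mean in the same way, with correlations across genes of 0.29, 0.67 and 0.43 for numbers 1, 2 and 3, and so were treated as pairs in the alternative that adds the number as a block. The pairing comes from these correlations and not from a label. They were printed in the same run as the blocked counts of calls, and Chat negative 1 correlated as well with Chat positive 3 (0.30) as with its own number. Alternatives chosen beforehand were RLE, upper-quartile and library-size scaling, no filter or at least 5 CPM in at least 3 libraries, the block, leaving out each library, DESeq2 with and without the block, limma-voom with and without sample weights, a fit without robust dispersions, a 10% threshold, glmTreat against a fold of 1.5, and camera with an estimated correlation, fry and rank-based camera for lists. Added after the data were seen were the blocked fit under other settings, fits without both libraries of a number, a per-library correction for transcript length and GC content (loess, span 0.4), and lists without Chat and Slc18a3.

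The models were tested on simulated data made from the 12967 genes' means, dispersions and number effects, with 200 genes changed in each of 20 runs. Without the block, 0.4%, 22.8%, 66.5% and 78.2% of genes changed 1.5-, 2-, 4- and 8-fold were found, and 0.297% of calls were false. With the block, 53.4%, 74.4%, 90.5% and 95.1% were found, but 15.8% of calls were false, above the 5% threshold. Blocked limma-voom and the blocked non-robust fit found 49.4% and 48.5% of the 1.5-fold changes, with 15.6% and 15.4% of calls false. The simulated number effects were the same in both gates, so the pairing was true by construction. The gain from the block therefore does not test the pairing of the real libraries. Nor are the false shares, with 200 changed genes per run, those of the calls in the real data. In 20 runs with no changed gene, the edgeR fit with the block still called a median of 11 genes (2 to 23), and the fit without it called 0. Camera called a list of 25 genes raised 1.4-fold in 10 of 10 runs and 0 of 300 unchanged lists. Several called lists moved much less than that, and these tables hold no correlation between genes beyond the number effects, so they do not test the preset correlation.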

Results

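RNA was sequenced from mouse ILC2s sorted by Chat, the acetylcholine-synthesising enzyme, into 3 Chat negative and 3 Chat positive samples. The Chat negative libraries held 42503612, 43097771 and 44061509 counts, and the Chat positive libraries 37154269, 50361306 and 40280664. Between 15335 and 16081 genes had a count in a library. The 50 most abundant genes took 16.8% ± 1.15 of counts in Chat negative and 17.1% ± 1.34 in Chat positive libraries (SD, n = 3 each, exact permutation p = 0.5). Mitochondrial genes took 0.220% ± 0.0533 and 0.250% ± 0.0394 (n = 3, exact permutation p = 0.5, higher in Chat positive for 3 of 3 numbers), and ribosomal protein genes 0.621% ± 0.0686 and 0.625% ± 0.0586 (n = 3, exact permutation p = 0.9). Some of these genes had almost no counts, with COX3 at 3 to 18 beside COX1 at 14089 to 30144. Rpl13 had 37 to 74 counts beside Rpl4 at 29123 to 37066. Such gaps limit what these shares, and the lists of these genes below, say about expression. Exact permutation p was 0.4 for genes with a count and 1 for total counts, and no measure could reach a p below 0.1 with 3 libraries per gate. These p-values leave the replicate numbers out. Xist had at most 5 counts in any library, while the Y-linked Ddx3y stood at 96.2 ± 16.0 CPM in Chat negative and 106 ± 14.8 in Chat positive cells.

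The gates were compared to find which transcripts separate ILC2s sorted as positive for the acetylcholine-synthesising enzyme from those sorted as negative. Chat itself rose from 20.2 ± 5.49 to 187 ± 17.9 CPM (n = 3 each), a 9.28-fold difference. It was higher in Chat positive cells for 3 of 3 replicate numbers. Slc18a3, which encodes the vesicular acetylcholine transporter, stood at 3.32 ± 1.02 CPM in Chat negative and 25.9 ± 8.99 CPM in Chat positive cells, with no overlap between the gates. The type 2 effector list, which holds Il5, Il13 and Areg, was higher as a set in Chat positive cells, while lists for glycolysis, lymphocyte transcription factors and ILC1 or NK cells were lower. In that order, adjusted p = 0.376, 0.489, 0.376 and 0.537 with an estimated correlation, so none of these 4 calls was kept.

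Chat (Entrez 12647, mm10 chromosome 14, 32408203 to 32465909) was the only gene past the threshold in this fit. The cells were sorted by Chat, so this call checks the labels, and no other gene passed. Its log2 change was 3.21 (SE 0.21), with an adjusted p of 0.0174 in edgeR's quasi-likelihood test. Chat included, 315 genes had an unadjusted p under 0.05. The libraries of the gates did not overlap for 1056 of 12967 genes, or 8.14%, against 10% by chance if all 6 libraries were exchangeable, which the replicate numbers make doubtful. DESeq2 called 3 genes, adding Slc18a3 and the Notch ligand Jag1, limma-voom called Chat alone, and limma-voom with sample weights called Chat and Slc18a3. With the replicate number as a block, the Chat call was lost (log2 change 3.24, edgeR adjusted p = 0.0961), unless robust dispersions were left out (0.00240). It was also lost without Chat negative 1 (adjusted p = 0.190), Chat negative 3 (0.198), Chat positive 1 (0.247) or Chat positive 3 (0.127), although its log2 change stayed between 3.09 and 3.46 when any library was left out. Over all alternatives its adjusted p ranged from 6.18e-71 to 0.484.

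**Figure D1:**
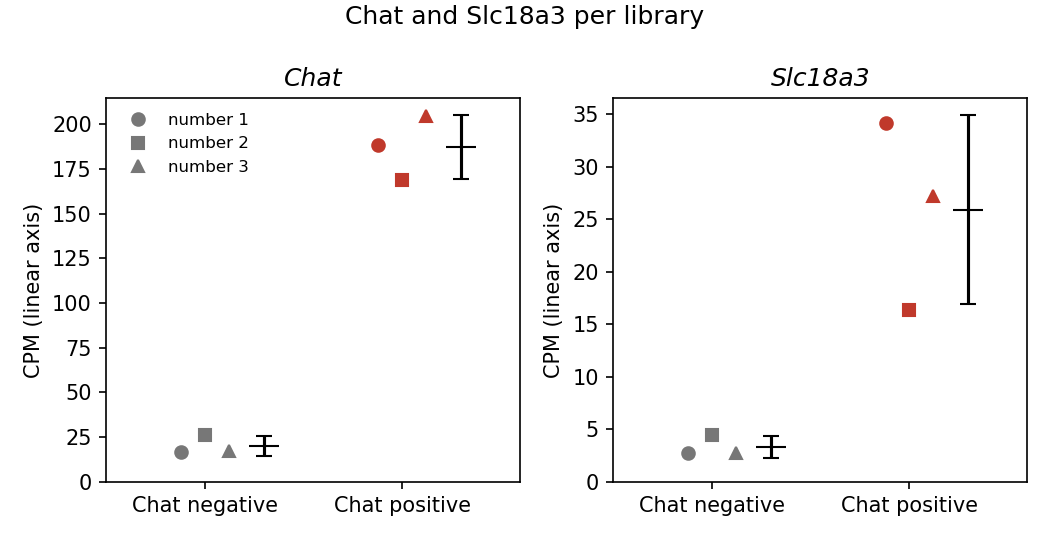
Chat and Slc18a3 in CPM per library on linear axes, with marker shapes for the replicate numbers and bars for the mean and SD of 3 libraries per gate. All 3 Chat positive libraries lie above all 3 Chat negative libraries for both genes, at 169 to 204 against 16.5 to 26.5 CPM for Chat.

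Slc18a3 (Entrez 20508, chromosome 14, 32462437 to 32464850) lies on the same strand as Chat, within the first intron of 4 annotated Chat transcripts, and overlaps no Chat exon in the GENCODE annotation of the same build. Its log2 change was 2.96 (SE 0.35), with an edgeR adjusted p of 0.403 that ranged from 2.51e-14 to 1.00 over the alternatives. The counting program is not known, so reads of unspliced Chat RNA over this intron cannot be told apart from Slc18a3 reads. Slc5a7, the high-affinity choline transporter that supplies acetylcholine synthesis in neurons, had 0 counts in all 6 libraries, as did Bche, a secreted cholinesterase. A count of 0 allows up to 3 counts, or 0.0807 CPM in the smallest library, for counting error alone.

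The acetylcholine synthesis, transport and breakdown list had 15 tested members. Chat passed over all genes, and Chat and Slc18a3 passed when adjusted over the list alone. The list was called higher (camera adjusted p = 2.87e-05), on a mean log2 change of 0.34 and a median of -0.01. Its adjusted p = 0.116 with an estimated correlation, 0.0822 with the replicate block and 0.413 without Chat and Slc18a3. Among members that did not pass, Pla2g15 stood at 22.5 ± 2.59 CPM in Chat negative and 17.7 ± 1.05 in Chat positive cells, and the choline transporter Slc44a1 at 21.7 ± 6.63 and 14.3 ± 2.28. The carnitine transporter Slc22a5 stood at 11.5 ± 1.20 and 12.7 ± 1.90 CPM, and Acly, which makes cytosolic acetyl-CoA, at 1101 ± 160 and 1013 ± 185. Colq, which anchors acetylcholinesterase, stood at 0.349 ± 0.233 and 0.211 ± 0.0990, and Slc44a5 at 0.317 ± 0.308 and 0.485 ± 0.140.

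Acetylcholine receptors and their regulators were sparsely expressed, with 7 of 24 listed genes tested. Lynx1, a membrane protein that dampens nicotinic receptors, stood at 1.801 ± 0.118 CPM in Chat negative and 1.04 ± 0.394 in Chat positive cells. The nicotinic subunit Chrnb1 stood at 3.30 ± 1.27 and 2.70 ± 0.211, and the receptor chaperone Ric3 at 1.79 ± 0.796 and 1.32 ± 0.610. The subunits Chrna2 and Chrnb2 and the muscarinic receptor Chrm4 averaged between 0.196 and 0.361 CPM in either gate. Ly6e, an abundant Lynx1 relative, stood at 3215 ± 626 and 2878 ± 703 CPM. The list had a median log2 change of -0.29 and a camera adjusted p of 0.0646, with none of its 7 members past the edgeR threshold.

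Type 2 cytokines and effector proteins, the products by which ILC2s act on other cells, formed the list with the highest median log2 change, 0.29, and 18 of 25 tested members were above 0. As a set they were higher in Chat positive cells (camera adjusted p = 2.87e-05), a call kept when any library was left out, but adjusted p = 0.376 with an estimated correlation. No member passed in edgeR without the block, either over all genes or adjusted over the list alone. With the block, 4 members were higher over all genes, and 14 were higher and 3 lower when adjusted over the list alone. Both counts are limited, because this fit also called genes in simulated tables with no changed gene. Blocked limma-voom and the blocked non-robust fit called no member over all genes. Il5, the eosinophil growth factor (Entrez 16191, chromosome 11, 53720794 to 53725103), stood at 7012 ± 1379 and 11186 ± 3208 CPM, a log2 change of 0.67 (SE 0.25). Il13, which drives mucus production (Entrez 16163, chromosome 11, 53631323 to 53634702), stood at 298 ± 27.6 and 423 ± 43.6 CPM, a log2 change of 0.50 (SE 0.12). Areg, an epithelial repair factor (Entrez 11839), stood at 243 ± 25.2 and 335 ± 32.1 CPM, a log2 change of 0.46 (SE 0.12). The anti-inflammatory cytokine Il10 (Entrez 16153) stood at 53.1 ± 4.86 and 74.9 ± 2.06 CPM, a log2 change of 0.50 (SE 0.11).

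Il4 stood at 53.4 ± 10.9 and 65.5 ± 16.7 CPM, the growth factor Csf2 at 31.2 ± 10.2 and 56.9 ± 27.6, and Arg1, an arginine-degrading enzyme of ILC2s, at 82.1 ± 32.7 and 100.2 ± 41.2. Calca, which encodes the neuropeptide CGRP, stood at 108 ± 63.7 and 164 ± 97.0 CPM, and the neutrophil-attracting chemokine Cxcl3 at 20.1 ± 16.4 and 36.5 ± 26.2. The TNF family member Tnfsf14 lay the other way, at 31.5 ± 1.27 in Chat negative and 22.4 ± 4.98 in Chat positive cells.

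**Figure D2:**
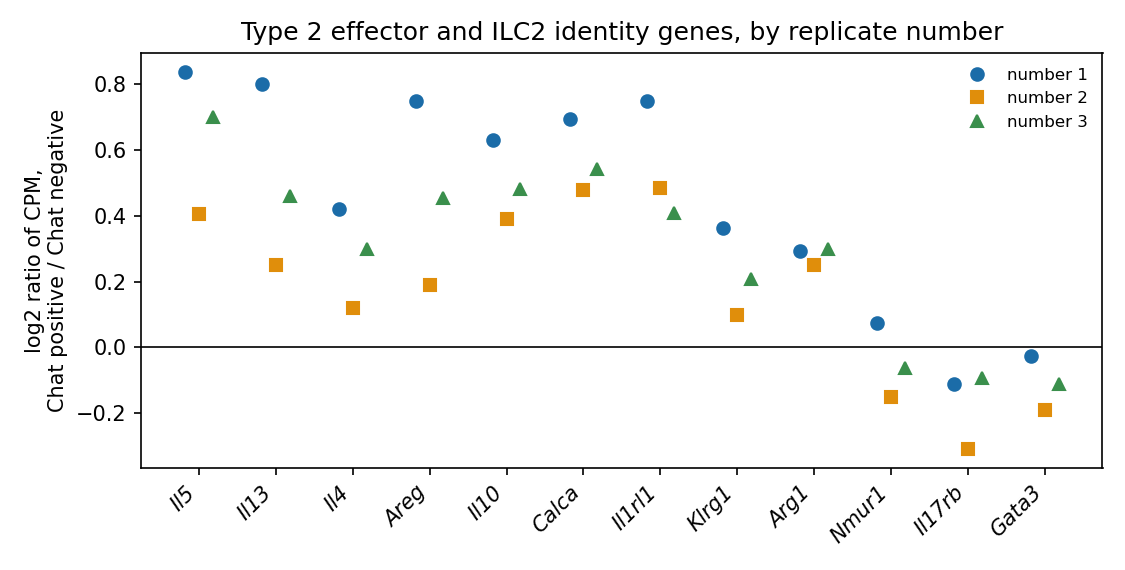
Log2 ratio of CPM, Chat positive over Chat negative, for each replicate number (marker shape and colour) in 12 type 2 effector and ILC2 identity genes. Il5, Il13, Il4, Areg, Il10, Calca, Il1rl1, Klrg1 and Arg1 lie above 0 for 3 of 3 numbers, while Gata3 and Il17rb lie below 0 for 3 of 3.

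Genes that define ILC2s did not move together between the gates. The ILC2 identity list had 13 of 28 tested members above 0, a median log2 change of -0.05 and a camera adjusted p of 0.826. Gata3, the transcription factor that specifies ILC2s, stood at 2281 ± 393 CPM in Chat negative and 2128 ± 456 in Chat positive cells. Il1rl1, the IL-33 receptor, stood at 85.9 ± 31.2 and 125 ± 39.2, and the surface receptor Klrg1 at 509 ± 27.5 and 597 ± 69.8. Nmur1, the neuromedin U receptor, stood at 567 ± 21.6 and 552 ± 62.7, and the IL-25 receptor Il17rb at 16.3 ± 2.23 and 14.4 ± 1.10. The inflammatory ILC2 program had a camera adjusted p of 0.387, with the serotonin-synthesis enzyme Tph1 at 938 ± 165 and 1332 ± 124 CPM and the AP-1 factor Batf at 296 ± 17.6 and 359 ± 33.7. Neuropeptide, catecholamine and lipid mediator receptors had an adjusted p of 0.757 over 34 tested genes. Among them Vipr1, a receptor for vasoactive intestinal peptide, stood at 1.41 ± 0.459 and 0.376 ± 0.288 CPM.

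By the naming rule, genes that did not pass but had the smallest p and no overlap between the gates included Nupr1, a stress-induced chromatin protein, at 38.2 ± 6.03 and 63.3 ± 1.93 CPM, and the checkpoint receptor Ctla4 at 81.0 ± 2.34 and 120 ± 17.7. The small GTPase Mras stood at 45.7 ± 0.290 and 62.6 ± 5.08, the elongation factor Ell2 at 46.2 ± 5.75 and 69.0 ± 7.96, the tautomerase Ddt at 43.6 ± 4.07 and 60.6 ± 4.19, and the casein gene Csn1s1 at 7.34 ± 3.72 and 20.9 ± 6.33. In the other direction, Jag1 (Entrez 16449, chromosome 2, 137081451 to 137116520) stood at 81.2 ± 10.3 in Chat negative and 44.5 ± 3.45 in Chat positive cells, a log2 change of -0.87 (SE 0.13), with an edgeR adjusted p of 1.00 and a DESeq2 adjusted p of 9.44e-04, within a range of 2.65e-17 to 1.00 over the alternatives. The giant scaffold protein Ahnak stood at 269 ± 36.97 and 164 ± 26.9 CPM, and the IQ-motif scaffold Iqgap2 at 94.5 ± 7.57 and 67.6 ± 2.67. The laminin chain Lamc1 stood at 117 ± 8.24 and 91.0 ± 2.302, the glucocorticoid-induced Fkbp5 at 165 ± 14.6 and 127 ± 4.58, and Arid5b at 73.6 ± 2.63 and 58.3 ± 2.74. The adhesion genes Cntn3, Itga2 and Dag1 had log2 changes of -1.10 (SE 0.30), -0.50 (SE 0.15) and -0.40 (SE 0.12).

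With the replicate number as a block, edgeR called 44 genes, 28 higher and 16 lower, with log2 changes of 0.28 to 1.58 in size. Each had the same direction for 3 of 3 numbers, which a blocked test on 3 pairs selects for, so it adds no support. Named by the rule and called here were genes such as Csn1s1 (1.58, adjusted p = 0.0141), Ell2 (0.58, 0.0312), Nupr1 (0.74, 0.0419), Il10 (0.50, 0.0419), Ctla4 (0.55, 0.0419), Il5 (0.65, 0.0472), Il1rl1 (0.55, 0.0419), Tnfaip3 (0.39, 0.0419) and Ccr1 (0.34, 0.0455) among the higher genes. Ahnak (-0.72, 0.0141), Jag1 (-0.86, 0.0186) and Iqgap2 (-0.48, 0.0472) were among the lower ones. Chosen after their values were seen were Calca (0.57, 0.0245), the cytokine Il24 (0.80, 0.0312), Cxcl3 (0.93, 0.0312), the G protein regulator Rgs1 (0.37, 0.0419), the costimulatory receptor Tnfrsf9 (0.28, 0.0472), Tmem158 (-1.14, 0.0419) and the antiviral protein Ifitm2 (-0.45, 0.0419). This fit also made a median of 11 calls in simulated tables with no changed gene. Without the libraries of number 1 it made 0 calls, with 1195 genes at an unadjusted p under 0.05. With the libraries of number 3 exchanged between the gates it made 81 calls, and with those of number 1 or number 2 exchanged 0 each. Corrected for transcript length and GC content it also made 0 calls, with 1745 genes at an unadjusted p under 0.05, while limma-voom with the block called 1 gene and DESeq2 with the block 453.

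Genes for energy metabolism showed small shifts as sets. Nuclear-encoded oxidative phosphorylation genes had a median log2 change of 0.10, with 34 of 42 above 0 and none past the threshold in edgeR, and were higher in Chat positive cells (camera adjusted p = 0.00550). For this list adjusted p = 0.792 with an estimated correlation, and the call was lost without Chat negative 1 (0.428), Chat negative 3 (0.140) or Chat positive 2 (0.239). A rank-based test with the block went from an adjusted p of 2.74e-04 to 0.691 after a correction for transcript length and GC content. Ndufa1, a complex I subunit, stood at 177 ± 18.8 and 208 ± 3.88 CPM, and Cox7b, of complex IV, at 135 ± 15.9 and 154 ± 8.74. Glycolysis genes had a median log2 change of -0.11, with 18 of 23 below 0 and none past the threshold, and were lower (camera adjusted p = 0.0210, adjusted p = 0.489 with an estimated correlation). That call was lost without Chat negative 1 (0.153), Chat negative 3 (0.165) or Chat positive 2 (0.322). The hexokinases Hk1 and Hk2 stood at 845 ± 31.2 and 745 ± 2.55 CPM and at 80.4 ± 8.22 and 62.4 ± 5.68, while Bnip3, a mitophagy receptor, stood at 552 ± 62.1 and 624 ± 87.0. Mitochondrially encoded genes, such as ND1 at 425 ± 110 and 536 ± 72.8, had 8 of 8 tested members above 0, with adjusted p = 0.0537 and, with the block, 0.00439, but adjusted p = 0.747 with an estimated correlation and the block. After the length and GC correction their median with the block went from 0.18 to -0.08, and the adjusted p of the rank-based test from 0.0130 to 0.636.

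Transcription factors of ILCs and T cells were lower as a set, with a median log2 change of -0.10 and 27 of 38 below 0 (camera adjusted p = 0.0419, adjusted p = 0.376 with an estimated correlation). None passed singly in edgeR. Foxo1, a regulator of lymphocyte quiescence, stood at 139.8 ± 18.5 CPM in Chat negative and 95.8 ± 18.0 in Chat positive cells, the repressor Zeb1 at 41.4 ± 2.70 and 32.0 ± 3.88, and Runx3 at 212 ± 27.7 and 173 ± 27.8. The call was lost without a low-count filter (0.0686), with the stricter one (0.116), and without Chat negative 1 (0.234), Chat negative 3 (0.0623) or Chat positive 2 (0.231).

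Markers of ILC1 and NK cells, the cytotoxic relatives of ILC2s, were lower as a set, with a median log2 change of -0.33 over 10 tested genes, 7 of them below 0 (camera adjusted p = 0.00912, adjusted p = 0.537 with an estimated correlation, 0.0673 with the block). The call was also lost with the stricter filter (0.0758) and without Chat negative 1 (0.424), Chat negative 3 (0.0623) or Chat positive 2 (0.176). The receptor gene Klrk1 stood at 3.16 ± 1.05 and 1.55 ± 0.670 CPM, Nkg7 at 17.4 ± 5.31 and 12.4 ± 4.24, and Il12rb2 at 1.43 ± 1.92 and 0.267 ± 0.218. The abundant granule genes Gzmb and Prf1 stood at 11668 ± 2404 and 11218 ± 852 CPM and at 83.8 ± 16.6 and 74.5 ± 15.3. Gzma, another granule gene of the list, went the other way for each number. It stood at 89.2, 15.0 and 65.4 CPM in Chat negative 1, 2 and 3, and at 119, 29.8 and 99.9 in Chat positive 1, 2 and 3. The list members Ncr1, Klrb1c and Eomes had at most 6 counts in a library and were not tested.

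Activation and checkpoint receptors had a median log2 change of 0.08, with 19 of 27 above 0, and a camera adjusted p of 0.0877 that became 0.0155 with the block, but adjusted p = 0.620 with an estimated correlation and the block. Cytokine receptors had an adjusted p of 0.0731, with Il2rb at 973 ± 43.9 and 825 ± 47.8 CPM and Il6st at 37.7 ± 5.97 and 28.8 ± 3.54. Migration and residency genes had an adjusted p of 0.104, and the integrin Itgae, which binds epithelial E-cadherin, stood at 654 ± 102 and 483 ± 37.8. The adjusted p was 0.605 for heat shock and dissociation stress genes, with the metallothionein Mt1 at 272 ± 31.0 and 203 ± 22.2 CPM and Gadd45b at 32.4 ± 1.25 and 41.5 ± 4.16. It was 0.678 for immediate early genes, with the NF-kappaB inhibitors Nfkbia at 299 ± 17.9 and 388 ± 52.8 and Tnfaip3 at 132 ± 29.0 and 173 ± 42.9. It was 0.381 for interferon-stimulated genes, with the RNA sensor Ddx58 at 157 ± 30.7 and 120 ± 15.5. S phase genes (0.787), G2 and M phase genes (0.605), cholesterol synthesis (0.784), lipid mediator synthesis (0.382), the unfolded protein response (0.412) and ribosomal proteins (0.787) did not pass either. The median, mean or test differed in sign for the lists of acetylcholine synthesis, ILC2 identity, inflammatory ILC2s, immediate early genes, cholesterol synthesis, ribosomal proteins and mast cells.

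Markers of other cell types described the purity of the gates. The tuft cell list was called higher (camera adjusted p = 1.09e-07), on Chat alone, with adjusted p = 0.116 with an estimated correlation and 0.826 without Chat. Of the tuft cell genes, Trpm5, Pou2f3, Il25 and Gnat3 had 0 counts in all 6 libraries, and Avil stood at 99.99 ± 29.8 and 102 ± 20.1 CPM. T cell markers had an adjusted p of 0.605, with Trgc1 at 261 ± 40.7 and 222 ± 35.0 and Lat at 155 ± 10.3 and 152 ± 13.1. B and plasma cell markers had an adjusted p of 0.826, with Ighm at 302 ± 51.2 and 241 ± 46.4 and H2-Ab1 at 272 ± 149 and 248 ± 128. For macrophage and dendritic cell markers it was 0.678, with Ccr2 at 823 ± 220.5 and 695 ± 151 and Cst3 at 138 ± 21.2 and 141 ± 32.8.

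Mast cell, basophil and eosinophil markers had an adjusted p of 0.678, with Cyp11a1 at 1875 ± 199.6 and 2160 ± 211 CPM and Kit at 190 ± 50.1 and 209 ± 61.1. For epithelial markers it was 0.787, with Epcam at 68.1 ± 28.8 and 46.5 ± 13.0 and Hopx at 55.9 ± 18.6 and 61.5 ± 16.7. For fibroblast, muscle and endothelial markers it was 0.826, with Pecam1 at 63.5 ± 15.4 and 72.8 ± 20.2 and Npnt at 26.6 ± 8.15 and 24.9 ± 9.64. ILC3 markers had an adjusted p of 0.288, with Ahr at 80.0 ± 10.6 and 74.0 ± 11.6 and Ltb at 91.7 ± 35.5 and 76.7 ± 28.2. Lists of neutrophil, neuronal, erythroid and sex-linked genes had fewer than 5 tested members and were not tested.

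**Figure D3:**
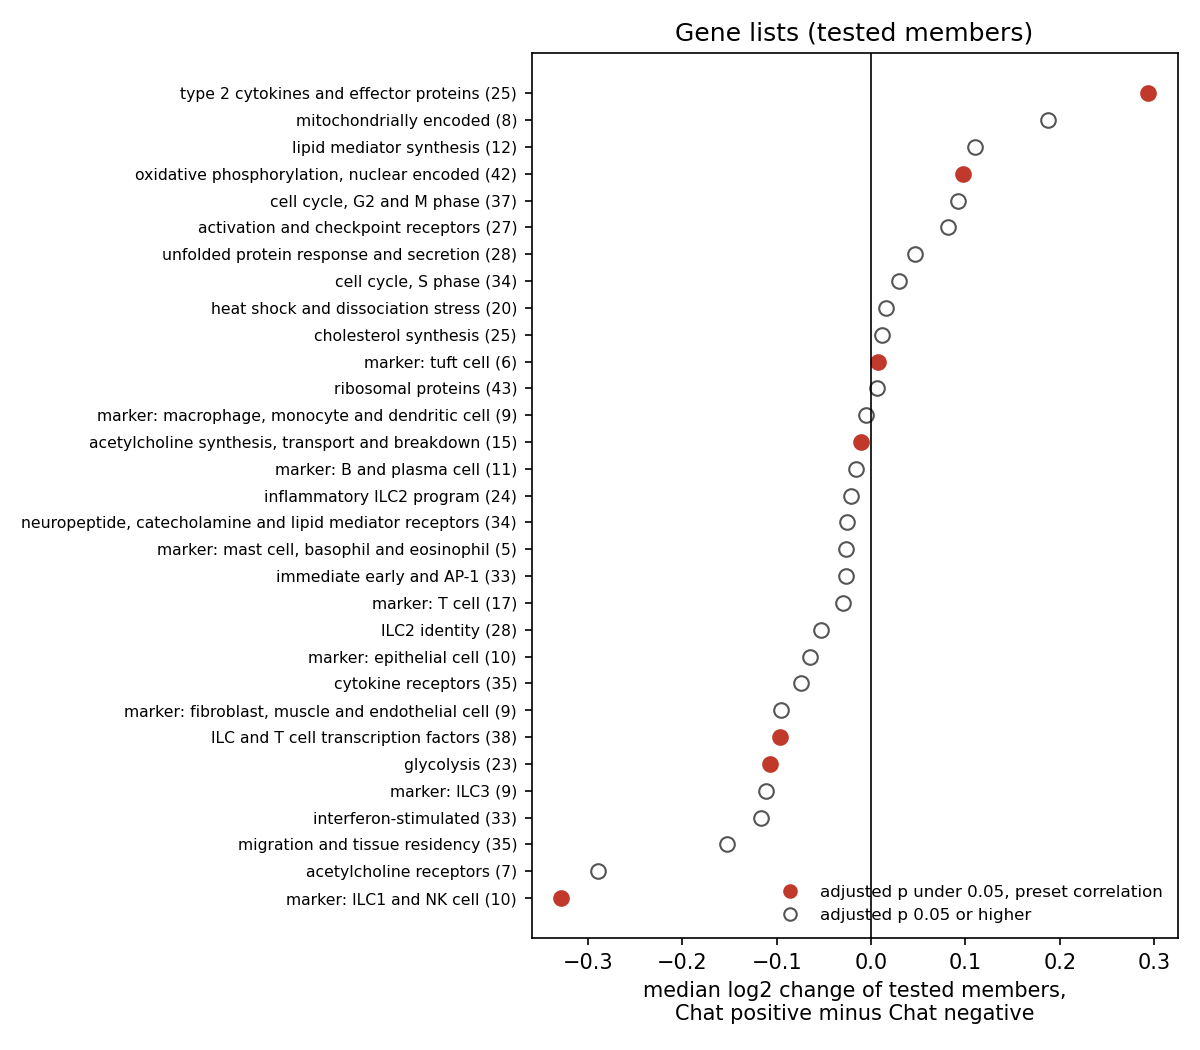
Median log2 change of the tested members, Chat positive minus Chat negative, for the 31 lists, with the number of members in brackets and filled points at a camera adjusted p under 0.05 with the preset correlation. Type 2 cytokines and effector proteins have the highest median, 0.29, and ILC1 and NK cell markers the lowest, -0.33.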

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

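The fits listed as added in the methods, including every variant of the blocked fit, were chosen after the result was seen. Chat was higher in Chat positive cells in every fit, and its call was kept with RLE, upper-quartile and library-size scaling, both filters, DESeq2, limma-voom, the non-robust fit and glmTreat. Its adjusted p in edgeR was lost with the replicate block (log2 change 3.24), and with the block under RLE scaling (3.23), library-size scaling (3.26), upper-quartile scaling (3.24), no filter (3.24), the stricter filter (3.24) and the length and GC correction (3.25). Without any library, or both libraries of a number, its log2 change ran from 3.08 to 3.53. With the block, the Chat call was kept in edgeR without robust dispersions (adjusted p = 0.00240). Blocked limma-voom (0.00163, and 0.00154 with sample weights) and blocked DESeq2 kept it too. With all 6 libraries, the block thus lost the call only in edgeR with robust dispersions. No cause beyond that was tested.

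The count of 1 called gene became 44 with the replicate block, 3 in DESeq2, 2 in limma-voom with sample weights and 453 (175 higher, 278 lower) in DESeq2 with the block. It ran from 0 to 1 without single libraries. It was 0 in edgeR without Chat negative 1, Chat negative 3, Chat positive 1 or Chat positive 3, with 136, 316, 175 and 350 genes at an unadjusted p under 0.05. The blocked count of 44 (28 higher, 16 lower) became 25 (22 higher, 3 lower) with library-size scaling, 182 with no filter, 72 with the stricter filter, 120 at the 10% threshold, 453 in DESeq2, of which 42 were shared, and 1, Chat, in limma-voom, in limma-voom with sample weights and in the non-robust fit. It became 0 in edgeR with the length and GC correction, with 1745 genes at an unadjusted p under 0.05. Without the libraries of number 1, 2 or 3 it was 0, 3 (Chat, Slc18a3 and Il5) or 709 (172 higher, 537 lower). The 44 genes kept their direction in the fits that measured them, except Tnfrsf9 without Chat negative 2 (-0.031). The causes were not tested.

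Of the lists, 7 were called (4 higher, 3 lower). The replicate block also called 7, of which 5 were shared, and changed no other list's call than those printed in the results. The count became 0 with an estimated correlation (2 lists at an unadjusted p under 0.05), 2 with fry, 3 with rank-based camera, 4 without Chat and Slc18a3 and 4 with rank-based camera after the length and GC correction, and ran from 3 (without Chat negative 1) to 13 (without Chat negative 2). With the block it became 0 with an estimated correlation and 0 with fry (6 lists at an unadjusted p under 0.05). The block leaves few residual degrees of freedom for a test with an estimated correlation, which limits what its lack of calls can show. Over all alternatives the adjusted p of called lists ran from 3.43e-10 to 0.620 for type 2 effectors, 1.94e-06 to 0.964 for acetylcholine synthesis, 6.51e-09 to 0.948 for tuft cells, 3.56e-06 to 0.792 for oxidative phosphorylation, 4.44e-04 to 0.620 for glycolysis, 0.00315 to 0.620 for transcription factors and 4.07e-05 to 0.641 for ILC1 and NK markers. The causes were not tested.

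Among named genes, 22 changed sign in at least 1 fit, none of them past the threshold without the block. The range over left-out libraries or numbers was -0.24 to 0.067 for Gata3, -0.053 to 0.60 for Arg1, -0.13 to 0.037 for Nmur1, -0.22 to 0.068 for Gzmb, -0.30 to 0.0035 for Prf1, -0.10 to 0.026 for Lat, -0.53 to 0.25 for H2-Ab1, -0.15 to 0.19 for Cst3, -0.11 to 0.38 for Kit, -0.11 to 0.35 for Hopx, -0.048 to 0.35 for Pecam1, -0.46 to 0.16 for Npnt, -0.55 to 0.0059 for Ltb, -0.20 to 0.21 for Avil and -0.031 to 0.57 for Tnfrsf9. For acetylcholine genes it was -1.50 to 0.039 for Colq, -0.015 to 0.31 for Slc22a5, -0.28 to 0.0049 for Acly, -0.59 to 0.12 for Chrnb1, -0.32 to 0.021 for Ly6e, -1.12 to 1.05 for Chrm4 and -0.58 to 0.63 for Chrnb2. Limma-voom with sample weights gave 0.0066 for Nmur1, -0.040 for Avil and -0.021 for Slc22a5. The length and GC correction gave -0.035 for Cst3, and -0.041 with the block. Chrm4 was -0.21 in limma-voom, -0.13 in DESeq2 with the block and -0.0058 with the block and no filter. Chrnb2 was -0.016 with the block, robust or not, -0.024 and -0.014 with the block under RLE and upper-quartile scaling, -0.060 with the block and no filter, -0.21 in limma-voom and -0.10 in DESeq2 with the block. The causes were not tested, and Chrm4 and Chrnb2 lay below 0.4 CPM on average, where depth limits the precision.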

Other observations

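The comparison of replicate numbers, the genes named for it and all tests of explanations were chosen after the result was seen, except the counts of other splits, which were planned. With the block in the edgeR model, more genes differed by replicate number (4208) than by gate (44). The first principal component held 52.8% of the variance and placed Chat negative 2 and Chat positive 2 at 52.4 and 46.6, against -33.9 to -16.2 for the other 4 libraries. Pairwise, 3672 genes passed between numbers 1 and 2, 4594 between numbers 2 and 3 and 0 between numbers 1 and 3. Each number has 2 libraries, so these tests set a difference between numbers only against the spread within a number, in a fit that makes too many calls on simulated data. Their p-values therefore describe these libraries alone.

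G2 and M phase genes, which run chromosome segregation, had a mean log2 CPM of 5.95, 6.95 and 5.69 in Chat negative 1, 2 and 3 and of 6.06, 6.99 and 5.71 in Chat positive 1, 2 and 3. Between numbers 1 and 2, 36 of 37 were called higher in number 2, with a median log2 change of 0.95 (camera adjusted p = 3.65e-54, adjusted p = 0.629 with an estimated correlation). The proliferation marker Mki67 averaged 109, 235 and 83.1 CPM in numbers 1, 2 and 3, topoisomerase Top2a 322, 606 and 256, and Rrm2, which makes deoxynucleotides, 394, 854 and 297. Interferon-stimulated genes went the other way, with 25 of 33 called lower in number 2 than in number 1 and a median log2 change of -0.92 (camera adjusted p = 4.02e-19, adjusted p = 0.629 with an estimated correlation). Also lower in number 2 than in number 1 were the lists of immediate early genes (camera adjusted p = 6.76e-05), type 2 effectors (0.00135), glycolysis (0.00202), macrophage and dendritic cells (0.00323, 5 of 9 genes called), ILC1 and NK cells (0.00348), epithelial cells (0.0153), activation receptors (0.0186) and ribosomal proteins (0.0352). The S phase list (camera adjusted p = 4.54e-29, 32 of 34 genes called) and oxidative phosphorylation (0.00429) were higher in number 2. Although no gene passed between numbers 1 and 3, number 3 had lower G2 and M phase (36 of 37 below 0, camera adjusted p = 1.85e-28), S phase (3.86e-15) and ILC1 and NK lists (0.0151), and higher mitochondrially encoded (8 of 8 above 0, 2.88e-14), interferon-stimulated (30 of 33 above 0, 8.16e-14) and type 2 effector lists (0.0182). None of these lists passed with an estimated correlation (adjusted p = 0.629 or higher). With the numbers and the gate in the model, that camera test had few residual degrees of freedom. Its smallest unadjusted p was 0.0165, for G2 and M phase genes between numbers 2 and 3, where 36 of 37 were called. Its lack of passing lists therefore cannot be read for or against them. The antiviral modifier Isg15 averaged 25.4, 6.43 and 45.9 CPM, the interferon regulator Irf7 55.1, 13.2 and 76.9, and Rtp4 26.9, 1.00 and 41.9. The effector genes Calca, Vegfa and Arg1 averaged 161, 46.2 and 200.5 CPM, 102, 40.0 and 124 CPM, and 92.2, 53.6 and 127 CPM. Of the 25 tested type 2 effector genes, 10 were called lower and 2 higher in number 2 than in number 1. Cxcl3 lay the other way, at 14.9, 52.85 and 17.2 CPM.

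This difference in G2 and M phase genes between numbers spanned 1.27 on the log2 scale, averaged over the gates. Depth is argued against, because the span was 1.26 among the Chat negative libraries, whose highest total is 1.04 times the lowest, and 1.28 among the Chat positive libraries, where it is 1.36 times the lowest. A smooth trend in transcript length and GC content is argued against as well, with a span of 1.24 after its correction. The median length of these genes, 3421 nt, was near the 3372 nt of all tested genes, so a length trend could move them little. Bias of another shape was not tested. Whether a number stands for an animal, a day or a culture is not given in the labels, so no biological explanation was tested, and a difference in proliferation between the mice or cultures stays open.

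The Chat negative libraries held Chat at 10.8% and Slc18a3 at 12.8% of their Chat positive levels. Chat positive cells inside the Chat negative gate may be the source, but cannot be told apart from low expression in all cells of that gate: the log2 changes of the genes differed by 0.25 (SE 0.41), and while Slc18a3 counts may come from unspliced Chat RNA their ratio would be the same at any purity. Slc18a3 counts were 16.4%, 17.0% and 15.6% of Chat counts in Chat negative 1, 2 and 3 and 18.2%, 9.70% and 13.3% in Chat positive 1, 2 and 3. The Slc18a3 counts may come from unspliced Chat RNA or from transcription of Slc18a3 itself. Reads per kb over Slc18a3 were at most 21.5% of those over the Chat exons in any library. Either source could give such a value, so both stay open.

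The genes called higher with the block had shorter transcripts (median 2115 nt) than those called lower (4267 nt). The correlation of log2 ratio and length across genes was -0.32, -0.093 and -0.12 for numbers 1, 2 and 3. A correction for transcript length and GC bias moved the correlation in the blocked fit from -0.26 to -0.05. No gene passed afterwards (edgeR, lowest adjusted p = 0.0521, 1745 genes at an unadjusted p under 0.05). The change kept cannot decide whether this bias is the whole cause. The genes were picked by their change in the same data, and the correction removes only a smooth trend. After it, the 44 genes kept a median of 87.9% of their log2 change. The median size of their log2 changes went from 0.52 to 0.47 and the median SE from 0.073 to 0.067, and the calls ended because p rose for 38 of the 44 (median 7.72e-05 to 1.75e-04): with only their own p replaced, 0 of the 44 passed, and with only the other genes' p replaced, 44 did. For lists tested by rank with the block, glycolysis (adjusted p = 6.81e-04 after the correction, median -0.12) and type 2 effectors (0.00989, median 0.32) kept their calls. The smooth trend that the correction removes was therefore not the whole source of these calls, but bias of another shape was not tested. With the block and an estimated correlation, camera gave an adjusted p of 0.620 for either list. The bias stays open for oxidative phosphorylation (0.691, median 0.10 before and 0.02 after), mitochondrially encoded genes (0.636, median 0.18 before and -0.08 after) and transcription factors (0.0405 before and 0.158 after, median -0.10 and -0.06). The correction moved other lists both ways, ending the call of G2 and M phase genes (0.0255 to 0.147) and making calls of ribosomal proteins (0.780 to 0.00989), interferon-stimulated genes (0.0596 to 0.0200) and ILC1 and NK markers (0.0633 to 0.0421), all 3 lower, and a biological difference between the gates may remain but is not separated from the false calls that this fit makes on simulated data.

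The splits of the 6 libraries were too few for a share under 0.05. Of the 10 splits into 3 and 3, 1 gave at least the real count of 1 called gene (highest other 0), and 4 gave at least the real count of 7 called lists (highest other 11). The 3 other splits with at least 7 lists part only 1 pair and so carry the difference between numbers. The 4 splits that part every pair called 7 (real), 4, 1 and 0 lists. With the block, 2 of these 4 gave at least the real count of 44 calls. The highest other, 81, exchanged the libraries of number 3 between the gates, and the 2 that exchanged number 1 or number 2 gave 0 calls each.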
